A study of Mus musculus with 4 samples.

How the data were processed

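Gene expression and T cell receptor sequences were measured in single CD4 T cells recovered from the spleens of 2 NOD.Rag1null hosts on day 14 after transfer of cells from B6.H2g7 donors aged 6 to 8 weeks, with 1 expression library and 1 receptor library per host. Per the submitters' processing notes, the 10x 5′ libraries were processed with Cell Ranger 7.0.1, with the genome builds mm10 and GRCm38 named. The deposited expression matrices hold counts, as UMIs per gene and cell barcode for the barcodes called cells by Cell Ranger, with no normalization. The deposited receptor tables hold read and UMI counts per assembled contig with its V and J genes and CDR3, and every contig in them is marked as productive, full length and of high confidence. The labels do not say whether cells of the donors were pooled before transfer, so p-values do not measure the spread between donors. In fits with the mouse as a block, differences between the hosts themselves are removed. Their p-values rest on how the difference between classes varied between these 2 hosts, mostly as a spread pooled across genes. The weight of the pooled spread is given as prior degrees of freedom. In the main fit of Vβ3 against other cells these were 102, against 1 residual. With 1 cell per clonotype and at matched cluster composition they were infinite in that comparison. There a gene's own variation between the hosts has no weight.

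Kept cells had at least 500 detected genes, at most 10% mitochondrial UMIs, exactly 1 productive TRB chain and at most 2 productive TRA chains. Of the barcodes, 9860 and 9642 passed the gene and mitochondrial filters, 6701 and 7034 of them had a TRB chain, and 708 (10.6%) and 702 (9.98%) with 2 TRB chains were left out. The kept cells held 38725969 and 44796902 UMIs, with medians of 2302 and 2501 genes and 1.64% and 1.66% mitochondrial UMIs. A clonotype was defined as the same TRBV, TRBJ and TRB CDR3 nucleotide sequence in 1 mouse. Vβ3 cells were those with TRBV26, and Vβ20 cells those with TRBV23. In comparisons of Vβ3 with other cells, other cells are all kept cells without TRBV26. Coordinates of V genes come from the GENCODE M21 basic annotation. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. The label of a cell as Vβ3 or not was checked against the leading V transcript, at a minimum of 2 UMIs, and was the same in 99.7% of 11624 cells. The match of other V calls was not computed.

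Cells were clustered with scanpy 1.11.5 on 2000 variable genes without T cell receptor genes, 30 principal components, 15 neighbours and Leiden resolution 0.6 with seed 0. Clusters were named from marker lists where enough markers led, and otherwise left unnamed. Cluster genes were ranked by fold over the remaining cells.

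UMI counts were summed per mouse and class, giving 4 sums with 1 residual degree of freedom per comparison, so the test leans on the spread pooled across genes. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, mouse as a block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. T cell receptor gene segments were left out of the tests because they define the classes. Fold changes are log2 values with their standard errors, and CPM are each gene's counts per 1000000 counts of its sum. In total 26 gene lists were fixed: naive, Treg, Th1, cytotoxic, Th2, Th17, Tfh, T cell receptor signal, inhibitory and exhaustion, anergy, proliferation, interferon response, helper cytokines and ligands, homing, apoptosis, glycolysis, dissociation stress, and markers of B, CD8 T, NK, myeloid, dendritic, erythroid, platelet, γδ T and invariant NKT cells. Of these, 23 had enough measured genes and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Members shared between lists count in each.

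The lists, the markers, the comparisons, most alternatives and the rule for naming genes were chosen before the data were examined. For Vβ3 against other cells, the rule names the 8 largest increases and 8 largest decreases among genes past the threshold with the same sign in both mice and at least 20 CPM in 1 class, the 2 members of each list with the smallest p, and Foxp3, Il2ra, Pdcd1, Ctla4, Il21, Ifng, Il2, Cd40lg, Mki67 and 1 more gene. For clonally expanded cells it names the 5 largest changes each way and 1 gene per T cell list, and for V genes TRBV26 with the 3 most and 3 least expanded. For each cluster it names the 5 genes with the largest fold. Of the genes the rule names, 1 chosen beforehand and 1 that led a cluster are not reported here. Genes outside the rule appear as members of a list that rose or fell, or are said to have been chosen after their values were seen.

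The tests were checked on simulated counts with known changes in 50 genes per fold. Counts were drawn independently for each gene at a single spread, the median fitted to the same sums. Changed genes were taken only from those above a minimum expected count. The false calls in such draws do not show how many real sums of clonal cells would give. For the sums of Vβ3 and other cells, 62% of genes changed 1.25-fold, 86% changed 1.5-fold, 94% changed 2-fold and 100% changed 4-fold were recovered, with 5 false calls among 12989 genes. For expanded against single cells the shares were 54%, 96%, 98% and 100%, with 8 false calls among 12587 genes. For TRBV19, as an example of a smaller class, they were 14%, 44%, 86% and 100%, with 2 false calls among 12996 genes.

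The likeness of each V gene to Vβ3 was measured as Pearson's r and covariance of log2 fold changes across genes, with the comparison cells split so that the classes shared none. For TRBV23 it was set against 100 draws of simulated unchanged groups of its size, with independent noise for each gene. Depth per cell was equalised by thinning to 3307 UMIs, which left out 1231 kept cells with fewer, 411 of them Vβ3. Alternatives covered the normalization, the test (DESeq2 1.42.0), filters on genes and cells, the mouse block, clonotype weight, class definition, doublets, depth, number of cells, cluster composition and leaving out each mouse. Doublet scores came from scrublet, which marked 0 of 19502 barcodes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used. Cells before transfer, other host strains and CD8 T cells were not analysed here.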

Results

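The study followed CD4 T cells from spleens of B6.H2g7 mice, a C57BL/6 background strain with the H2g7 major histocompatibility haplotype of NOD mice, after transfer into NOD.Rag1null hosts, which lack T and B cells of their own. Per the labels, 5000000 column-purified cells were transferred, and live cells positive for CD4 and the T cell receptor β chain were sorted from host spleens on day 14. From each of 2 hosts, called mouse 1 and mouse 2 here, a 5′ gene expression library and a T cell receptor library were made. The libraries form 1 group, so every comparison below is between classes of cells within the same mice. The gene expression files held 9996 and 9733 cell barcodes with 70092822 and 75940181 UMIs, and the receptor files held 15865 and 16275 contigs of 7587 and 7763 barcodes. After filtering, 5993 and 6332 cells with exactly 1 productive TRB chain were kept, at medians of 5596 and 6219.5 UMIs per cell. They formed 3166 and 3316 clonotypes, and 60.04% and 59.2% of the kept cells belonged to clonotypes with 2 or more cells.

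The title of the series concerns CD4 T cells with the receptor segment Vβ3 and a mouse mammary tumor virus, a family whose superantigens bind T cell receptors through the β-chain V segment. Vβ3 is encoded by Trbv26 (ENSMUSG00000076479), a V segment gene with 2 exons on the plus strand of chromosome 6, 41227505 to 41227993 in GRCm38. TRBV26 was the most frequent of all V genes in both mice. It was carried by 2084 cells of mouse 1, 34.8% of the kept cells (95% exact binomial interval 33.6 to 36.0), and by 1960 cells of mouse 2, 31.0% (29.8 to 32.1), with a mean of 32.9% ± 2.70 (SD, n = 2 mice). Among clonotypes, each counted once, the shares were 45.7% (43.9 to 47.4) and 43.0% (41.3 to 44.7), with a mean of 44.3% ± 1.89 (SD, n = 2). The next V gene was TRBV23, which encodes Vβ20, with 16.002% and 11.4% of cells and 20.1% and 15.3% of clonotypes. Trbv23 (ENSMUSG00000076478) lies on the plus strand of chromosome 6 at 41216073 to 41216526 in GRCm38 and also has 2 exons. Across 21 V genes seen in both mice, the shares of cells had a Pearson's r of 0.962 between mice and a Spearman's rho of 0.826. Over the 19 V genes without TRBV26 and TRBV23 r was 0.561 and rho 0.765. These correlations are across V genes, which are not independent replicates, so no p is given. These shares were not tested across the 2 mice, and the intervals cover counting error only.

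**Figure D1:**
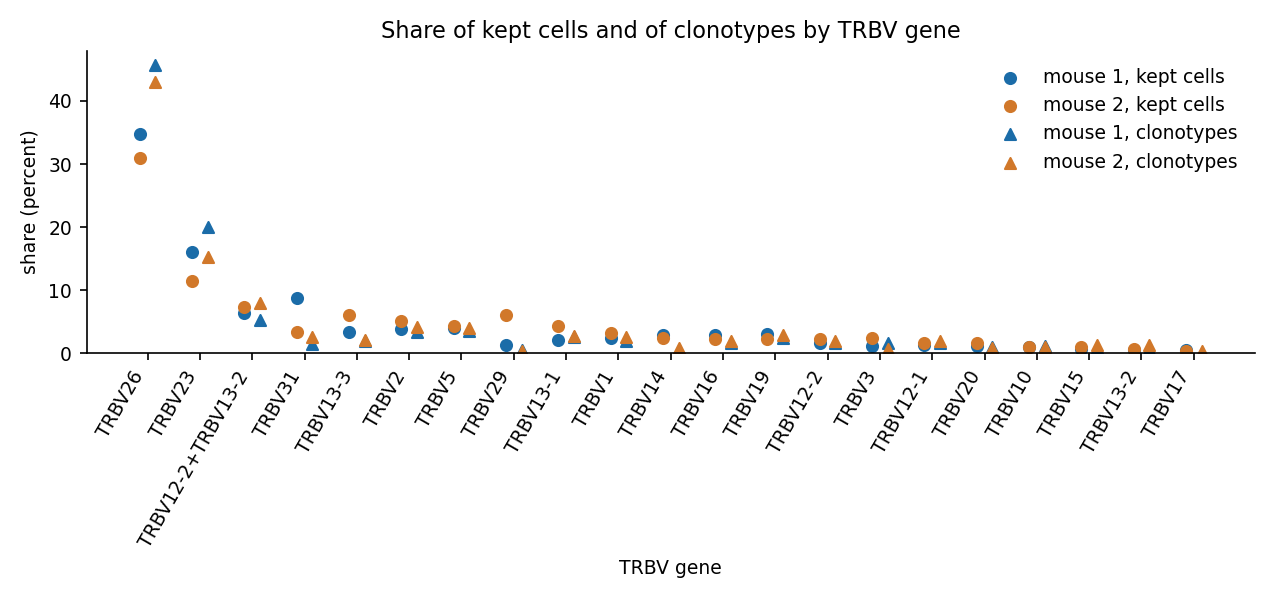
Share of kept cells (circles) and of clonotypes (triangles), in percent, for each TRBV gene seen in both mice, with mouse 1 in blue and mouse 2 in orange. TRBV26 holds 34.8% and 31.0% of cells and 45.7% and 43.0% of clonotypes, above every other V gene in both mice.

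The Vβ3 cells were spread over many small clonotypes, with 1.44 and 1.37 cells per clonotype. Clonotypes of 2 or more cells still held 45.3% and 40.7% of them. With every V gene drawn to 100 cells per mouse, TRBV26 gave 95.6 and 95.2 clonotypes per 100 cells, against means of 48.8 and 53.9 over the 11 other V genes with at least 100 cells in each mouse. The difference averaged 44.0 ± 3.94 (SD, n = 2 mice). TRBV23 came next with 92.8 and 90.0, followed, by the mean of both mice, by the V call TRBV12-2+TRBV13-2, for which the deposited table names both genes, with 61.8 and 78.6. In mouse 1 TRBV13-1 ranked above that call, with 68.8. The lowest V genes by that mean were TRBV14 with 13.2 and 18.8, TRBV13-3 with 34.4 and 27.3, and TRBV31 with 14.5 and 48.3 clonotypes per 100 cells. This measure depends on how many clonotypes a V gene has as well as on their size. In mouse 2 TRBV19 and TRBV23 had 1.42 and 1.43 cells per clonotype, but 75.0 and 90.0 clonotypes per 100 cells. The largest clonotypes of mouse 1 used TRBV31 and held 222 cells (3.70%) and 216 cells (3.60%), and the largest of mouse 2 used TRBV29 and held 366 cells (5.78%). The largest Vβ3 clonotypes held 36 cells (0.601%) in mouse 1 and 59 cells (0.932%) in mouse 2.

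**Figure D2:**
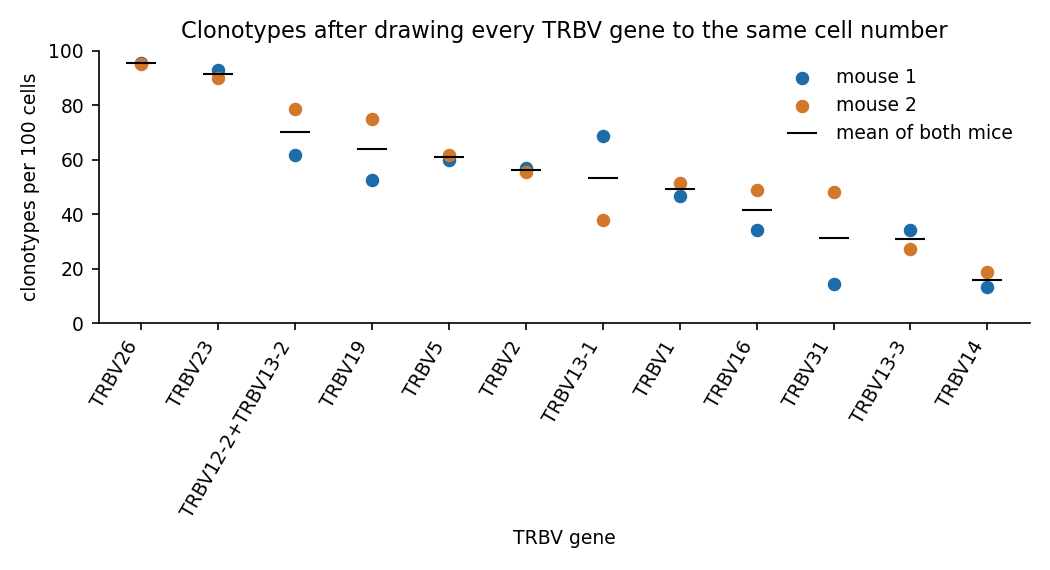
Clonotypes per 100 cells after drawing each TRBV gene to 100 cells in each mouse (points) and the mean of both mice (bars), for the 12 V genes with at least 100 cells per mouse. TRBV26 lies at 95.6 and 95.2 and TRBV14 at 13.2 and 18.8.

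Receptor contigs and V transcripts were compared cell by cell. A Trbv26 UMI was found in 99.4% and 99.8% of Vβ3 cells and in 5.66% and 4.94% of the cells with neither TRBV26 nor TRBV23, at median depths of 5411.5 and 6261.5 against 5726.5 and 6201 UMIs. At least 2 Trbv26 UMIs were found in 96.8% and 98.5% of Vβ3 cells and in 0.780% and 0.905% of those other cells. Among the barcodes that passed the gene and mitochondrial filters, 29.4% and 24.9% had no receptor contig. Trbv26 was the leading V transcript in 28.5% and 11.3% of those without a contig that had a leading transcript, against 35.9% and 32.0% of the kept cells. By leading transcript over all barcodes past the cell filters, the Vβ3 share was lower, 33.1% and 25.8%. These barcodes also include ones with contigs that were not kept.

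Clustering of the kept cells gave 10 clusters, of which 5 could be named from the marker lists. A Treg-like cluster, led by Foxp3, Rln3, Itgae, Penk and Cep112, held 13.1% and 16.9% of cells. A Th1 effector-like cluster (Ccl5, Gcg, Gzmk, Ccl4) held 18.8% and 13.1%. Another (Cx3cr1, Klra3, Spp1, Klrd1, Ccl3) held 8.81% and 14.8%, but its name is weak, since its top 10 genes held 1 Th1 marker (Ly6c2) and 1 NK cell marker (Klre1). A naive-like cluster (Igfbp4, Ifitm1, Ly6c1, Ifitm2, Dapl1) held 7.34% and 10.5%, but its name may not cover all its cells, since its top 10 genes also held the Th17 marker Tmem176b. When all barcodes past the cell filters were clustered, Igfbp4, Ly6c1 and Dapl1 led a naive-like cluster. Ifitm1, Ifitm2 and Tmem176b were then among the leading genes of a separate Th17-like cluster. A proliferating-like cluster (Hist1h2ae, Ube2c, Pclaf, Birc5, Hist1h1b) held 6.72% and 4.31% of the kept cells. The largest cluster, led by Sostdc1, Id3, B630019A10Rik, Il4 and Ces2c, stayed unnamed and held 30.2% and 28.2% of cells. Other unnamed clusters were led by Hs6st3, Ext1, Plcl1, Maml2 and Smyd3 (7.74% and 5.01%), by Nrgn, Xcl1, Ccl1, Tprg and Igfbp7 (3.44% and 4.04%), by Crtam, Samd3, Cldn10, Xcl1 and Ptprk (3.34% and 2.24%), and by H2-Aa, H2-Ab1, H2-Eb1, C1qb and C1qa (0.517% and 0.916%). When cells were clustered without the 2951 genes that differed between Vβ3 and other cells, the counterpart of the cluster led by Sostdc1 and Id3 held 39.0% and 48.6% of Vβ3 cells against 18.2% and 17.7% of the other cells.

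The comparison of Vβ3 cells with all other cells asked which transcripts differed between the receptor class named in the title and the remaining CD4 T cells of the same hosts. Id3 (ENSMUSG00000007872), an inhibitor of E-protein transcription factors, was higher in Vβ3 cells, at 306.9 ± 22.4 against 134.1 ± 23.1 CPM (mean ± SD, n = 2 mice), a log2 fold change of 1.20 (SE 0.0400, edgeR adjusted p = 1.50e-49). Tcf7, which encodes the transcription factor TCF1, rose by 0.92 (SE 0.0346), from 323.0 ± 4.65 to 612.4 ± 39.7 CPM. The glutathione S-transferase gene Gstp2 rose by 1.496 (SE 0.0469). Spp1, the gene of the secreted phosphoprotein osteopontin, fell by 4.13 (SE 0.0990) on the log2 scale. Igfbp4 fell by 3.89 (SE 0.0933), Ly6c1 by 4.09 (SE 0.152) and the chemokine gene Xcl1 by 2.84 (SE 0.112). The mice differed by more than these SEs, which pool the spread across genes. After adding 1 CPM, mouse 1 and mouse 2 gave -3.09 and -4.32 for Igfbp4, -4.20 and -3.20 for Ly6c1, and -3.67 and -1.98 for Xcl1.

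In total 2951 of 12989 tested genes passed the threshold, 1319 higher and 1632 lower in Vβ3 cells, and 2940 of them had the same sign in both mice. The largest increases also included B630019A10Rik (log2 fold change 1.5002), Gm20400 (1.46), Bace2 (1.39), Ces2c (1.29), Gm14718 (1.28) and 8030451A03Rik (1.17), and the largest decreases 5830405F06Rik (-2.13), Gzma (-1.89), Susd2 (-1.85) and Plac8 (-1.82). Without the mouse as a block 272 genes passed, 125 higher and 147 lower, all 272 among the 2951, DESeq2 called 685, and Bace2 (adjusted p = 0.149) was lost. In DESeq2 Plac8 was not called (adjusted p = 0.181), and it was -0.97 in mouse 1 and -2.48 in mouse 2 after adding 1 CPM. A further fit held the 12 V genes with at least 100 cells in each mouse as separate classes and left out cells of rarer V genes. TRBV26 was set against the unweighted mean of the others, so a lost or turned call can also reflect this other comparison. In this fit of 12 V genes 657 genes passed and 27 of the named genes lost their calls. Among them 5830405F06Rik (0.29, adjusted p = 0.816) and Cd74 (0.10, 0.935) turned. Others lost the call but kept their sign: Spp1 (-2.68, adjusted p = 0.0572), Gzma (-1.76, 0.149), Ccl5 (-0.67, 0.531), Fasl (-0.88, 0.0501), Eomes (-0.91, 0.109), Tmem176a (-1.18, 0.0769), Tmem176b (-1.25, 0.116), Klre1 (-2.17, 0.120) and Ighm (-0.55, 0.265). Some decreases shrank with 1 cell per clonotype: Susd2 to -0.62, Nr4a2 to -0.61, Xcl1 to -2.02 and Klre1 to -1.49. Others grew, among them Foxp3 from -0.76 to -1.45, Il2ra from -0.84 to -1.43, Ccr4 from -1.25 to -2.05, Mki67 from -0.61 to -1.05, Rrm2 from -0.70 to -1.13 and Ighm from -0.63 to -1.18. When the other cells were drawn to the cluster composition of the Vβ3 cells, 394 genes passed, and the calls of Id3 (log2 0.07, adjusted p = 0.467), Tcf7 (0.11, adjusted p = 0.0609), Ces2c, Gm14718 and 8030451A03Rik ended. The clusters were made from such genes, and Id3, Ces2c and Tcf7 rank high in the largest one. A call that ends at matched composition, here and below, can therefore end in part by construction.

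**Figure D3:**
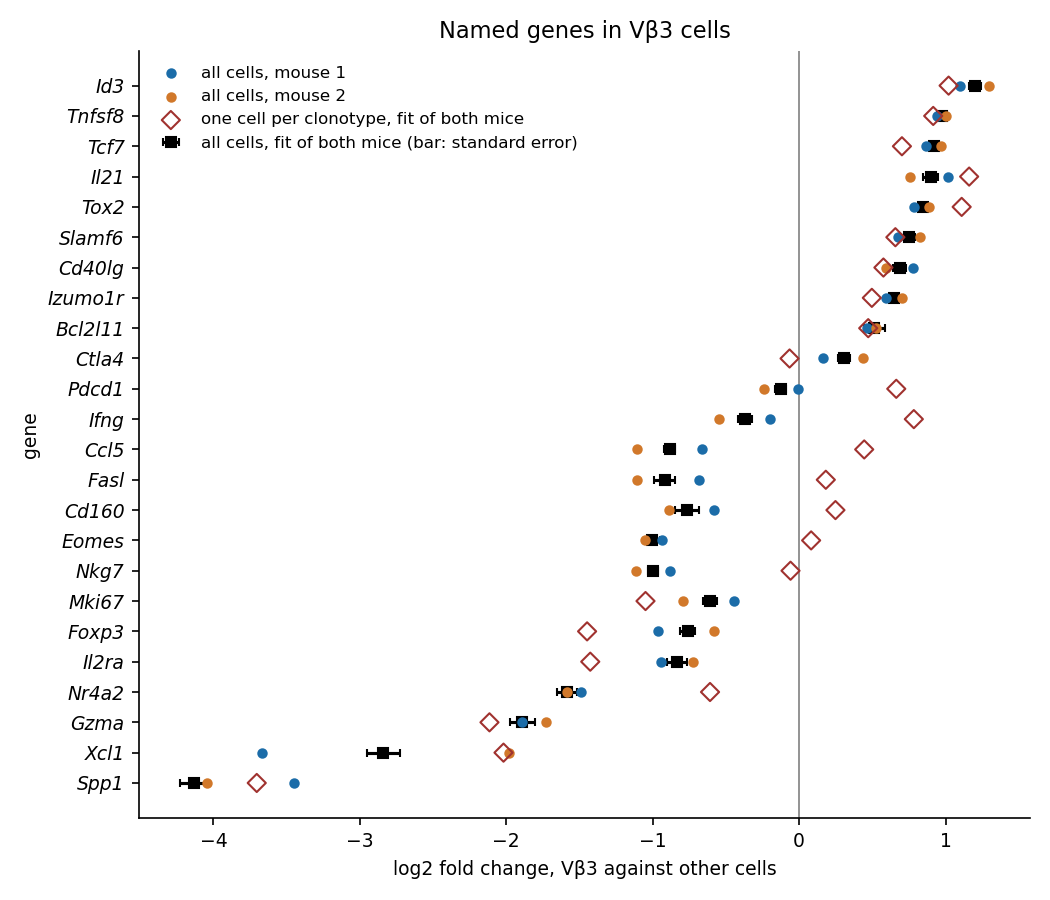
Log2 fold change of 24 named genes in Vβ3 against other cells, from the fit of both mice (black squares, bars for the standard error), in each mouse alone after adding 1 CPM to both classes, which pulls genes of low level toward 0 (blue and orange points) and with 1 cell per clonotype (open diamonds). Id3 lies at 1.20 and Spp1 at -4.13, and Ccl5 lies at -0.88 with all cells and at 0.44 with 1 cell per clonotype.

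Genes of follicular helper T cells were mostly higher in Vβ3 cells: 11 of 13 list members rose, 1 fell and 1 was not called, the same counts when adjusted over the list alone (camera adjusted p = 6.97e-26, adjusted p = 0.359 with an estimated correlation). Slamf6, a receptor of T and B cell contacts, rose by 0.75 (SE 0.0374), Tox2 by 0.85 (SE 0.0466) and the cytokine gene Il21 by 0.90 (SE 0.0513), from 58.0 ± 2.89 to 109.0 ± 19.2 CPM. Pdcd1, which encodes PD-1, was the member that fell, by 0.12 (SE 0.0378, edgeR adjusted p = 0.00831), with -0.01 in mouse 1 and -0.24 in mouse 2. Of 13 helper cytokines and ligands 9 rose, 3 fell and 1 was not called (camera adjusted p = 2.44e-10, adjusted p = 0.359 with an estimated correlation). Tnfsf8, the CD30 ligand gene, rose by 0.98 (SE 0.0383) and Cd40lg, whose product activates B cells and dendritic cells, by 0.69 (SE 0.0462), while Il2 fell by 1.10 (SE 0.213). Of 12 anergy genes 7 rose, 1 fell and 4 were not called, or 2 lower over the list alone (camera adjusted p = 1.86e-04, adjusted p = 0.359 with an estimated correlation), with Izumo1r, the folate receptor 4 gene, at 0.65 (SE 0.0328) and Nt5e, which encodes CD73, at 0.39. The 15 genes that respond to T cell receptor signals split into 7 higher, 4 lower and 4 not called (camera adjusted p = 0.930), with Egr1, Egr2 and Egr3 among the higher and Nr4a2 (-1.58, SE 0.0681) and Tnfrsf9 (-1.02) among the lower. With matched cluster composition Tox2, Tnfsf8 and Cd40lg lost their calls (adjusted p = 0.0917, 0.724 and 0.507), and the Tfh, helper cytokine and anergy lists lost theirs. Tnfsf8 ranks high in the largest cluster, so its loss follows in part from the match itself. In the fit with no mouse block 6 Tfh genes, 6 helper cytokine genes and 1 anergy gene were called higher, and Pdcd1 (adjusted p = 0.569), Il2 (0.217) and Nt5e (0.134) were not called.

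Effector genes were lower in Vβ3 cells when every cell counted. Of 16 Th1 genes 11 fell, 3 rose (Il12rb2, Cxcr3 and Stat4) and 2 were not called, or 12 and 4 adjusted over the list alone (camera adjusted p = 9.45e-14, adjusted p = 0.440 with an estimated correlation). Of 12 cytotoxic genes 11 fell and Klrg1 rose (camera adjusted p = 4.99e-48, adjusted p = 0.359 with an estimated correlation). Nkg7, a granule protein gene of cytotoxic cells, fell by 1.00 (SE 0.0330), the chemokine gene Ccl5 by 0.88 (SE 0.0357) and Fasl, the Fas ligand gene, by 0.92. Ifng fell by 0.37 (SE 0.0479). Of 13 genes of inhibitory receptors and exhaustion 11 fell, 1 rose and 1 was not called, or 12 lower over the list alone (camera adjusted p = 5.41e-13, adjusted p = 0.359 with an estimated correlation). Eomes, a T-box factor of effector cells, fell by 1.00 (SE 0.0528), and Ctla4 was the member that rose, by 0.31 (SE 0.0403). With 1 cell per clonotype several of these turned: Ccl5 was 0.44, Fasl 0.18, Eomes 0.08, Pdcd1 0.66, Ifng 0.78 and Ctla4 -0.07, Nkg7 was -0.06 (adjusted p = 0.337), and of the Th1 genes 6 were higher and 2 lower. The Th1 list was then called upward (camera adjusted p = 1.12e-04, adjusted p = 0.452 with an estimated correlation), while the calls of the cytotoxic list (3 genes higher, 5 lower, 0.396) and of the exhaustion list (4 higher, 3 lower, 0.179) ended. The call of Ifng also ended at matched cluster composition (adjusted p = 0.648). The calls of Ifng (adjusted p = 0.371), Ctla4 (0.366) and Eomes (0.0836) ended without the mouse block, where 3 Th1, 5 cytotoxic and 4 exhaustion genes were called lower.

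Genes of naive cells and of cell division were lower in Vβ3 cells. Of 14 naive and quiescence genes 7 fell, 2 rose (Tcf7 and Lef1) and 5 were not called (camera adjusted p = 1.11e-08, adjusted p = 0.359 with an estimated correlation). Counting 1 cell per clonotype, 13 fell and 1 rose, at a median of -0.56 instead of -0.22. Of 16 homing receptor genes 10 fell, 2 rose and 4 were not called (camera adjusted p = 1.44e-07, adjusted p = 0.359 with an estimated correlation), and the integrin gene Itgb1 rose by 0.45. All 22 measured proliferation genes fell (camera adjusted p = 7.24e-27, adjusted p = 0.359 with an estimated correlation), among them Mki67, a marker of cycling cells, by 0.61 (SE 0.0479), Stmn1 by 0.62 and Rrm2 by 0.70. Without the mouse block edgeR called 0 of the 22 proliferation genes (7 at an unadjusted p under 0.05; Mki67 adjusted p = 0.459, Stmn1 0.377, Rrm2 0.324), DESeq2 with the block called 14, Itgb1 (0.0797) was lost, as it was at matched cluster composition (0.563), and 3 naive and 2 homing genes were called lower.

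Foxp3 (ENSMUSG00000039521), the lineage factor of regulatory T cells, was lower in Vβ3 cells, at 74.6 ± 20.9 against 125.8 ± 11.9 CPM (mean ± SD, n = 2), a log2 fold change of -0.76 (SE 0.0516, edgeR adjusted p = 7.35e-25), and Il2ra, which encodes CD25, fell by 0.84 (SE 0.0685). Of 14 Treg genes 9 fell, 2 rose (Izumo1r and Ctla4) and 3 were not called, the same counts adjusted over the list alone (camera adjusted p = 4.36e-08, adjusted p = 0.448 with an estimated correlation). The calls of Foxp3 (adjusted p = 0.0996) and Il2ra (0.158) ended without the mouse block, where 2 Treg genes were called lower, and they also ended with matched cluster composition (Foxp3 at -0.12, adjusted p = 0.378). Both genes rank high in the Treg-like cluster, so the match evens them out in part by construction. In the fit of 12 V genes as separate classes, Foxp3 lay at -0.45 (adjusted p = 0.501).

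The Treg-like cluster held 153 of 2084 Vβ3 cells of mouse 1, 7.34% (6.26 to 8.55), and 233 of 1960 of mouse 2, 11.9% (10.5 to 13.4), against 16.1% (15.002 to 17.3) and 19.1% (17.97 to 20.3) of the other cells. The difference averaged -8.02 percentage points ± 1.11 (SD, n = 2 mice), and -17.1 points with 1 cell per clonotype. A Foxp3 UMI was found in 7.34% and 11.3% of Vβ3 cells against 16.3% and 17.8% of other cells after thinning every cell to 3307 UMIs, and in 8.49% and 12.96% against 18.98% and 20.4% without thinning. In thinned cells of both Th1 effector-like clusters, which should lack the gene, it was found in 0.761% and 0.977%, at medians of 5371 and 5777 UMIs before thinning, and in thinned Treg-like cells in 77.1% and 81.3%, at 6032 and 6347 UMIs. Among Vβ3 cells the Treg-like share was 9.84% and 16.4% in clonotypes of 2 or more cells and 5.27% and 8.78% in clonotypes of 1 cell. Among other cells it was 13.3% and 15.4% in the larger clonotypes and 22.1% and 26.8% in clonotypes of 1 cell. When each larger clonotype counted as 1 cell its share was 20.9% (17.3 to 24.9) and 31.3% (27.1 to 35.7) among other cells, without the drop, and 7.49% (4.81 to 11.03) and 14.8% (10.7 to 19.6) among Vβ3 cells.

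**Figure D4:**
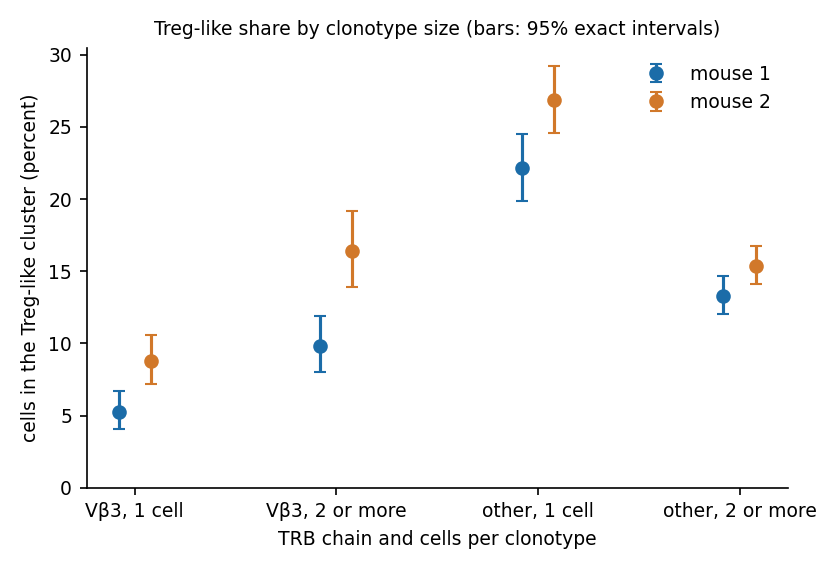
Percent of cells in the Treg-like cluster (points, with 95% exact binomial intervals for counting error) for Vβ3 and other cells in clonotypes of 1 cell and of 2 or more cells, in mouse 1 and mouse 2. The share is 5.27% and 8.78% for Vβ3 clonotypes of 1 cell and 22.1% and 26.8% for other clonotypes of 1 cell.

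The remaining T cell lists were compared in the same way. Of 6 Th2 genes 2 rose, among them Il4, 2 fell, the chemokine receptor genes Ccr4 (-1.25) and Ccr8 (-0.81), and 2 were not called, or 3 lower over the list alone (camera adjusted p = 0.0823). Of 9 Th17 genes 5 fell, 1 rose and 3 were not called, or 6 lower over the list alone (camera adjusted p = 5.78e-05, adjusted p = 0.359 with an estimated correlation), with the ion channel genes Tmem176a and Tmem176b at -1.30 and -1.29. They were -0.43 (adjusted p = 0.320) and -0.64 (adjusted p = 0.00370) at matched cluster composition. Of 15 interferon response genes 4 rose, 2 fell and 9 were not called (camera adjusted p = 0.427), and Ifi27l2a was 0.29 and Slfn1 0.28 higher. Counting 1 cell per clonotype, 0 of these 15 rose and 6 fell, and camera called the list downward (adjusted p = 0.0168, adjusted p = 0.622 with an estimated correlation). Ifi27l2a (0.04, adjusted p = 0.563) and Slfn1 (0.11, adjusted p = 0.124) were then not called. Of 15 apoptosis regulators 3 rose, 3 fell and 9 were not called, or 5 lower over the list alone (camera adjusted p = 0.629). Among those that rose was Bcl2l11, which encodes the death factor BIM, at 0.51 (SE 0.0711), a call that was also made with matched cluster composition (0.57, SE 0.0885). Of 13 glycolysis genes 5 fell and 8 were not called, or 6 over the list alone (camera adjusted p = 0.0534), with the lactate transporter gene Slc16a3 at -0.59 and Ldha at -0.16. Of 11 dissociation stress genes 2 rose, 1 fell and 8 were not called (camera adjusted p = 0.427), Fosb at 0.43 and Hspa8 at -0.13. Ccr8, Ifi27l2a, Slfn1, Slc16a3, Ldha, Fosb and Hspa8 were not called without the mouse block (adjusted p = 0.110 to 0.912), nor were any of these 7 at matched cluster composition. Where list members went both ways, the sign of the median could differ from that of the mean or test: the interferon median was -0.01 and its mean 0.01, and the T cell receptor signal median was 0.02 and its mean -0.01, both tested upward.

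Markers of other cell types were measured beside these groups. Of 4 B cell genes 3 fell in Vβ3 cells (camera adjusted p = 6.50e-04, adjusted p = 0.359 with an estimated correlation), with Ighm at -0.63 and Ighd at -1.96, and of 5 NK cell genes 2 fell, 1 rose and 2 were not called (camera adjusted p = 1.70e-04, adjusted p = 0.359 with an estimated correlation), with Klre1 at -2.55. Of 10 myeloid genes 6 fell and 4 were not called (camera adjusted p = 0.00373, adjusted p = 0.371 with an estimated correlation). The neutrophil genes S100a8 and S100a9 were -1.72 and -2.73 overall but 0.02 and -0.19 in mouse 2 after adding 1 CPM, where their levels were under 1 CPM, so both values rest on mouse 1. Of 4 dendritic cell genes Cd74 fell (-0.16, but 0.08 and not called at matched cluster composition) and 3 were not called (camera adjusted p = 0.334), with H2-Aa at -0.24 (adjusted p = 0.303), 0.80 in mouse 1 and -1.35 in mouse 2. Of 5 erythroid genes 0 passed in edgeR, at an unadjusted p under 0.05 or in DESeq2 (camera adjusted p = 0.849, median 0.08, mean -0.09), Car2 at -0.78 (adjusted p = 0.187) and Hbb-bs at 0.09 (0.522). Hbb-bs was unstable, at -3.32 with 1 cell per clonotype (adjusted p = 6.20e-127), -3.76 with clonotypes of 1 cell alone, -0.76 with other cells drawn to the number of Vβ3 cells and -2.54 without the cluster led by myeloid genes. It was 2.03 at matched cluster composition, 1.99 without TRBV23 cells, 2.35 in the fit of 12 V genes and 1.84 without the Treg-like and proliferating-like clusters. All 8 values were called, so no direction is read from this gene. Of 4 genes of invariant NKT cells Klrb1c rose by 1.74 (0.38 and not called with matched cluster composition, adjusted p = 0.516), 2 fell and 1 was not called, or 2 and 2 over the list alone (camera adjusted p = 0.571, median -0.07, mean 0.21, tested downward). Cd160 was -0.76, but 0.25 (adjusted p = 0.112) with 1 cell per clonotype and not called in the fit of 12 V genes (adjusted p = 0.0869). The CD8 lineage gene Cd8b1 was -0.03 (adjusted p = 0.929). Platelet and γδ T cell genes did not reach the count filter. Ighd (adjusted p = 0.0983), S100a8 (0.707), S100a9 (0.553) and Cd74 (0.370) were not called without the mouse block.

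In all, camera called 14 of 23 lists, 3 higher and 11 lower, and 0 with an estimated correlation (1 at an unadjusted p under 0.05, lowest adjusted p = 0.359). Fry, which asks whether a list moves on balance in 1 direction, called 0 (6 at an unadjusted p under 0.05, lowest adjusted p = 0.158), and 3 without the mouse block. Counting 1 cell per clonotype, camera called 15 lists, 4 higher and 11 lower. The Th2, interferon, dendritic and erythroid lists were then called lower, the cytotoxic, exhaustion and myeloid lists were not called, and the Th1 list turned. With that weight 0 were called with an estimated correlation (1 at an unadjusted p under 0.05, lowest adjusted p = 0.427) and 0 by fry (6 at an unadjusted p under 0.05, lowest adjusted p = 0.182).

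The same fit was run for each of the other 11 V genes against all remaining cells. A median of 209 genes passed, from 3 for TRBV16 to 684 for TRBV23, against 2951 for TRBV26. With Vβ3 cells left out of the comparison cells the median fell to 15, from 2 for TRBV2 to 1742 for TRBV23, 795 higher and 947 lower, and with TRBV23 cells left out 3140 passed for TRBV26. With every V gene drawn to 125 cells per mouse, 511 genes passed for TRBV26, a median of 125 for the others, and at most 330 (TRBV14). With 1 cell per clonotype the numbers were 2872, 320 and 797 (TRBV2), and without the mouse block 272, 7 and 145 (TRBV13-3). The 684 genes of TRBV23 became 274 at 125 cells, 330 with 1 cell per clonotype and 23 without the mouse block. All these counts also depend on how strongly each fit pooled the spread across genes, so they are no even scale between V genes. With all cells the prior degrees of freedom were 6.75 for TRBV16, 16.4 for TRBV23 and 102 for TRBV26. TRBV16 went from 3 genes to 43 at 125 cells and 211 with 1 cell per clonotype, though both settings hold fewer cells.

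TRBV23 cells, singled out after the values were seen, had a profile close to that of Vβ3 cells. Against all cells with neither TRBV23 nor TRBV26 they showed higher Tnfsf8 (log2 fold change 1.59, SE 0.0625), Il21 (1.59, SE 0.0827), Id3 (1.501, SE 0.0667) and Tcf7 (1.06, SE 0.0574), and lower Foxp3 (-1.14, SE 0.0912). Markers of other cell types were higher as well: 3 of 5 erythroid genes (median 3.43), 4 of 9 myeloid genes (S100a9, S100a8, Lyz2 and Fcer1g) and 2 of 3 dendritic cell genes (H2-Aa and H2-Ab1). The cluster led by H2-Aa and C1qb held only 3 and 6 TRBV23 cells, 0.313% and 0.828%, against 0.441% and 0.960% of the cells with neither. In mouse 2 S100a8 and S100a9 were near the floor, at 0.13 and 0.22 CPM over all cells without Vβ3. The cluster led by Sostdc1 and Id3 held 47.9% and 53.8% of TRBV23 cells and 50.1% and 54.3% of Vβ3 cells, but 10.4% and 9.13% of the cells with neither. With separate comparison cells for each class, the log2 fold changes of TRBV23 and of Vβ3 had a Pearson's r of 0.815 across 6575 genes, which are not independent replicates, with a covariance of 0.0606. The next V call, TRBV12-2+TRBV13-2, had an r of 0.166. For TRBV23, 100 simulated unchanged groups of its size gave at most 0.0395, with a mean covariance of 1.80e-05. These draws hold no variation between clonotypes or clusters and set no bound for the smaller classes, whose r lay between -0.115 and 0.166. Against the same comparison cells r of TRBV23 was 0.936 and the covariance 0.0664, where the simulated groups averaged 0.353 and 0.00203. Against these same cells, 720 of 12327 genes were called higher and 875 lower in both classes, counts that shared comparison cells raise. Compared with each other directly, Vβ3 and TRBV23 cells differed in 37 of 11816 genes, 7 higher and 30 lower in Vβ3 cells.

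**Figure D5:**
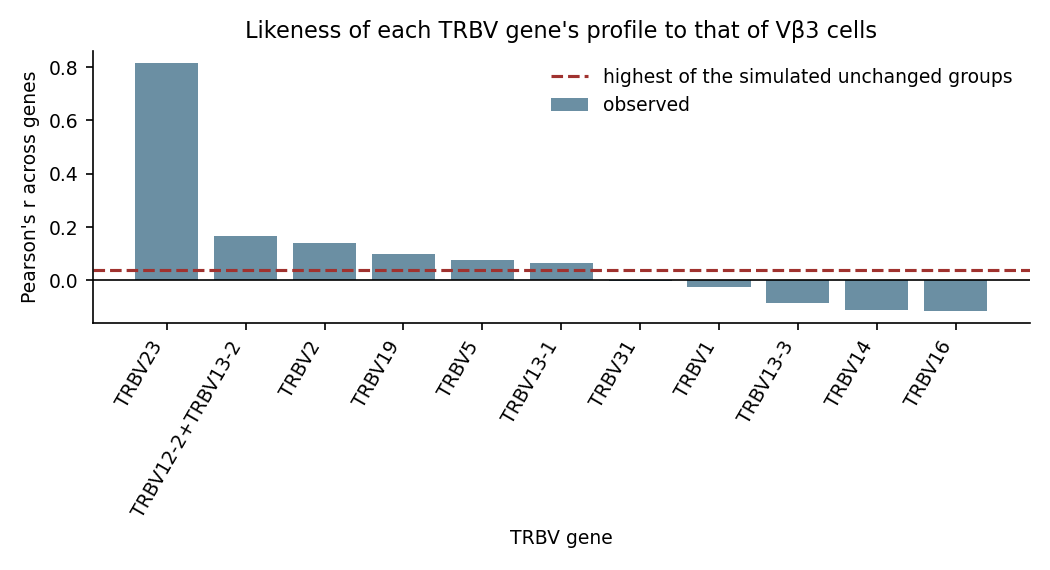
Pearson's r across genes between the log2 fold changes of each TRBV gene and those of Vβ3 cells, with separate comparison cells (bars), and the highest r of 100 simulated unchanged groups sized as TRBV23 (dashed line). TRBV23 lies at 0.815, above the simulated 0.0395, and the other V genes lie between -0.115 and 0.166. The line is no bound for those smaller classes.

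Clonally expanded cells were compared with cells of clonotypes seen once, among cells without Vβ3. Expanded cells had more transcripts of inflammatory chemokines: Ccl3 was 638.3 ± 16.97 against 67.1 ± 9.65 CPM (mean ± SD, n = 2), a log2 fold change of 3.25 (SE 0.0687, edgeR adjusted p = 7.19e-11), Ccl5 rose by 2.78 (SE 0.110) and Ccl4 by 2.52 (SE 0.0716). Igfbp4 fell by 5.25 (SE 0.0795), Ly6c1 by 5.09 (SE 0.169), and Ccr7, the lymph node homing chemokine receptor gene, by 2.43 (SE 0.0683). In total 2753 of 12587 genes passed, 1366 higher and 1387 lower. Ildr1 (2.77) and Prr5l (2.66) were the other largest increases, and Dapl1 (-3.98) and Pdlim4 (-3.93) the other largest decreases. Without the mouse block 1023 genes passed, 488 higher and 535 lower, and DESeq2 called 900 genes. At 1 cell per clonotype 1527 passed and the changes were smaller, with Ccl3 at 1.46, Ccl5 at 1.38, Ccl4 at 1.28, Ildr1 at 1.34, Prr5l at 1.35, Dapl1 at -2.95 and Ccr7 at -1.98.

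Effector lists rose with clonal expansion. Of 16 Th1 genes 11 rose, or 12 adjusted over the list alone, and 5 were not called (camera adjusted p = 2.99e-36, adjusted p = 0.529 with an estimated correlation), with Ifng at 2.07 (SE 0.0885). Of 12 cytotoxic genes 10 rose, Gzma fell and 1 was not called (camera adjusted p = 8.62e-56, adjusted p = 0.529 with an estimated correlation), with Gzmk at 2.10 and Fasl at 2.00. Of 13 inhibitory and exhaustion genes 11 rose, Ctla4 fell by 0.30 and 1 was not called (camera adjusted p = 2.01e-29, adjusted p = 0.529 with an estimated correlation), with Eomes at 2.19, Nr4a2 at 2.09 and Pdcd1 at 1.44 (SE 0.102). Of 22 proliferation genes 10 rose, or 14 adjusted over the list alone, and 12 were not called (camera adjusted p = 0.00123, adjusted p = 0.672 with an estimated correlation), with Mcm5 at 0.50 and Mki67 at 0.19 (adjusted p = 0.0311). Of 14 naive genes 12 fell and 2 were not called, or 14 fell over the list alone (camera adjusted p = 8.73e-89, adjusted p = 0.529 with an estimated correlation). Of 14 Treg genes 10 fell, Tnfrsf9 rose and 3 were not called, or 11 fell over the list alone (camera adjusted p = 8.42e-06, adjusted p = 0.529 with an estimated correlation), with Foxp3 at -0.61 (SE 0.0585), Il2ra at -0.71 and Itgae, the αE integrin gene, at -0.74. Without the mouse block edgeR called 0 proliferation genes (6 at an unadjusted p under 0.05; Mcm5 adjusted p = 0.118, Mki67 0.663), DESeq2 with the block called 3, edgeR called 4 Treg genes lower, and Il2ra (0.0827) and Ctla4 (0.0855) were lost. With 1 cell per clonotype Ifng was 1.05, Gzmk 1.23, Fasl 0.87, Eomes 1.03, Nr4a2 0.80 and Pdcd1 0.80. The Treg list turned, with 6 genes higher and none lower (camera adjusted p = 3.40e-04, adjusted p = 0.630 with an estimated correlation), Foxp3 was 0.13 (adjusted p = 0.162), Il2ra 0.19 (0.199), Ctla4 0.24 and Itgae 0.04, and 21 of 22 proliferation genes were higher.

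Interferon response genes were lower in expanded cells: 11 of 15 fell, or 13 adjusted over the list alone, and 4 were not called (camera adjusted p = 1.51e-10, adjusted p = 0.529 with an estimated correlation), with the antiviral gene Slfn5 at -0.999 (SE 0.0797). Of 10 Th17 genes 6 fell and 4 were not called, or 8 fell and 1 rose over the list alone (camera adjusted p = 1.55e-05, adjusted p = 0.529 with an estimated correlation), with the aryl hydrocarbon receptor gene Ahr at -1.50. Of 6 Th2 genes 2 fell and 4 were not called, or 4 fell over the list alone (camera adjusted p = 0.0461, adjusted p = 0.543 with an estimated correlation), with Ccr4 at -1.22. Of 13 Tfh genes 5 rose, Il21 by 0.43 among them, 3 fell and 5 were not called, or 4 fell over the list alone (camera adjusted p = 0.331, upward, with a mean of 0.15 and a median just under 0). Of 13 helper cytokines and ligands 7 fell, among them Il2 (-1.92) and Cd40lg (-0.53), 4 rose and 2 were not called, or 8 fell over the list alone (camera adjusted p = 0.599). The T cell receptor signal list had 6 higher and 5 lower of 15 genes, or 7 lower over the list alone (camera adjusted p = 0.560, median -0.01, mean 0.03). The anergy list had 4 higher and 3 lower of 12, or 4 lower over the list alone (0.497, median 0.02, mean -0.05), Dgka at -0.60 among them. The homing list had 4 higher and 8 lower of 16, or 9 lower over the list alone (0.229). Of 15 apoptosis regulators 5 rose and 3 fell (camera adjusted p = 0.101), and of 13 glycolysis genes 4 rose, Tpi1 by 0.35 among them, and 9 were not called, or 5 rose over the list alone (0.0757). Of 11 dissociation stress genes 5 fell and 6 were not called (camera adjusted p = 0.0120, adjusted p = 0.535 with an estimated correlation). Among markers of other cells, 2 of 4 B cell genes fell, or 3 over the list alone (camera adjusted p = 0.00143, adjusted p = 0.529 with an estimated correlation), 2 of 4 invariant NKT genes rose and 1 fell (camera adjusted p = 0.0375, adjusted p = 0.543 with an estimated correlation), and the NK, myeloid, dendritic and erythroid lists were not called (camera adjusted p = 0.331, 0.0782, 0.352 and 0.599). They had 2 higher and 2 lower of 5 genes, 3 and 1 of 9, 2 and 1 of 4, and 0 and 3 of 5, and Cd8b1 was not called. In all, camera called 12 of 23 lists, 5 higher and 7 lower, and 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called the stress list (adjusted p = 0.0129). With 1 cell per clonotype camera called 10 lists, 7 higher and 3 lower, and 0 with an estimated correlation (1 at an unadjusted p under 0.05, lowest adjusted p = 0.534). Fry then called 0 (3 at an unadjusted p under 0.05, lowest adjusted p = 0.112). At that weight Slfn5 was -0.42, Ahr -0.97 and Ccr4 -0.55. Without the mouse block Il21 (adjusted p = 0.0994) and Tpi1 (0.142) were not called and 8 interferon genes were called lower.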

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

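The tests of the cell cycle genes, of the differences between expansion effects with 1 cell per clonotype, of clusters of other cells and of depth per barcode were chosen only after the results were seen. What drew attention first was that clonotypes of 2 or more cells differed from clonotypes of 1 cell in other ways among Vβ3 cells than among other cells. A test of the difference between these 2 expansion effects called 787 of 12017 genes in edgeR, 46 without the mouse block and 79 with 1 cell per clonotype. The log2 difference was positive for Foxp3 (1.54, SE 0.143), Il2ra (1.06), Mki67 (0.77) and Ctla4 (0.58), and negative for Ifng (-1.70, SE 0.161) and Pdcd1 (-1.31, SE 0.138). Markers of other cell types differed as well: 3 of 5 erythroid genes were called positive (list median 5.14), as were Ighm (1.24) and Cd74 (0.52), and what other cells or their RNA add to the difference was not tested. Within Vβ3 cells Foxp3 was 0.93 higher (SE 0.0763) in clonotypes of 2 or more cells, while in other cells it was -0.61 (SE 0.0585). Without the mouse block only the difference of Pdcd1 passed among these genes (adjusted p = 0.0310), while Foxp3 (0.0770), Ifng (0.0601), Il2ra (0.413), Ctla4 (0.418) and Mki67 (0.679) did not.

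A few large Vβ3 clonotypes, doublets and dividing cells were weighed as technical explanations of the Treg and cell cycle genes in expanded Vβ3 clonotypes, and large clonotypes of either class as an explanation of the difference between Vβ3 and other cells. Within Vβ3 cells Foxp3 was 0.85 higher (SE 0.121) with 1 cell per clonotype and 1.03 without the proliferating-like cluster. These values argue against large clonotypes and dividing cells as the whole cause of its rise there. It was 0.97 higher with the highest doublet scores left out. That value cannot decide on doublets, since scrublet marked 0 barcodes and its scores did not set doublets apart. In other cells Foxp3 moved from -0.61 to 0.13 (SE 0.0605, adjusted p = 0.162) with 1 cell per clonotype. The difference between the 2 effects was then 0.71 for Foxp3 (SE 0.166, adjusted p = 0.0366), -0.78 for Ifng (SE 0.137) and -0.73 for Pdcd1 (SE 0.0942), each within its SE of the bound set for the test, so how much of it large clonotypes make stays open. For Il2ra (0.100, SE 0.226), Mki67 (-0.09) and Ctla4 (-0.19) little of it was left, which is what large clonotypes as its cause would give. The 22 cell cycle genes had a median of 1.02 in Vβ3 cells without the highest doublet scores, which leaves doublets open for the same reason. With 1 cell per clonotype their median was 0.50 (median SE 0.128, 12 of 22 called) against 0.98 with all cells, so a part played by large clonotypes stays open, and the median of 0.47 without the proliferating-like cluster decides nothing, since that cluster is defined by such genes. No biological explanation was tested, since the hosts are of 1 kind.

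Barcodes without a receptor contig, which the comparisons leave out, carried Vβ3 transcripts: at least 2 Trbv26 UMIs were found in 29.99% of them in mouse 1 and 17.5% in mouse 2, against 0.780% and 0.905% of kept cells with neither TRBV26 nor TRBV23. Clusters led by erythroid or antigen presentation genes held 3.00% and 2.25% of them, which argues against cells other than T cells as the main source, and thinned Cd3e UMIs of all barcodes without a contig were 0.989 and 0.889 times those of the kept cells. Their median depth was at least 1.22 times that of the kept cells, which argues against shallow barcodes, and thinned Trbc UMIs were 1.08 times as many in each mouse, which argues against little receptor RNA. No biological explanation was tested, and loss in the receptor library could not be examined from the filtered contigs.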

How the results depend on the processing

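The alternatives without TRBV23 cells, without the cluster led by myeloid genes, with the largest clonotypes out, with 1 cell per clonotype and no block, by leading transcript, by unthinned Foxp3, with clusters made without the called genes, with lists at matched composition, for the difference between expansion effects, for the other V genes without Vβ3 cells, and with the top 8% of doublet scores out (in place of the planned scrublet marks, not run because 0 barcodes were marked) were chosen after seeing the data. Of 1583 values of named genes under an alternative, 1250 kept direction and side of the threshold, 111 fell short of it, 8 newly passed and 41 turned, and with 1 mouse left out, where no p can be computed, 58 more stayed within the SE of the main value and 115 moved further; the cause was not tested unless stated. Genes that passed between Vβ3 and other cells numbered 685 in DESeq2, 272 without the block, 646 with 1 cell per clonotype and no block, 1843 after thinning (fewer UMIs), 394 at matched cluster composition, 657 in the fit of 12 V genes, and 2383 to 3140 under all others. For expanded cells they numbered 900 in DESeq2, 1023 without the block, 1527 with 1 cell per clonotype, and 2738 to 3467 otherwise. For the difference between the expansion effects of Vβ3 and other cells they numbered 787, 46 without the block and 79 with 1 cell per clonotype. The median of the other V genes was 125 (highest 330) at equal cells, 320 with 1 cell per clonotype, 7 (highest 145) without the block and 15 (highest 1742) with Vβ3 cells left out of the comparison cells. Camera lists fell from 14 to 0 with an estimated correlation and 0 by fry. The Vβ3 share was 29.4% by leading transcript, the difference in clonotypes per 100 cells was 33.7 without the largest clonotypes, and the Treg-like difference was -17.1 with 1 cell per clonotype and -6.06 with clusters made without the called genes. Leaving out 1 mouse gave 31.0% to 34.8% of cells, 43.0% to 45.7% of clonotypes, 41.3 to 46.8 clonotypes per 100 cells and -8.80 to -7.23 points. Without the block 26 genes named by the rule lost their calls, and between expanded and single cells Il2ra, Ctla4, Il21 and Mki67 lost theirs as well.

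Values that turned, as log2 between Vβ3 and other cells, were with 1 cell per clonotype Ccl5 0.44, Eomes 0.082, Fasl 0.18, Hbb-bs -3.32, Cd160 0.25, Pdcd1 0.66, Ctla4 -0.065 and Ifng 0.78, and Itgae 0.043 between expanded and single cells; with no block as well, Ccl5 0.45, Eomes 0.062, Fasl 0.19, Cd160 0.26, Pdcd1 0.66, Ctla4 -0.061 and Ifng 0.79. With only clonotypes of 1 cell they were Nkg7 0.16, Ccl5 0.72, Eomes 0.24, Fasl 0.37, Hbb-bs -3.76, Cd160 0.31, Pdcd1 0.90, Ctla4 -0.014 and Ifng 1.08. At matched cluster composition they were Nt5e -0.0100, Slc16a3 0.0018, Ldha 0.062, Hspa8 0.0031 and Cd74 0.080, and in the fit of 12 V genes 5830405F06Rik 0.29 and Cd74 0.10. With other cells drawn to the number of Vβ3 cells S100a8 was 0.75 and Hbb-bs -0.76, without TRBV23 cells S100a8 was 0.50, and leaving out 1 mouse put S100a8 between -1.47 and 0.024. Without the Treg-like and proliferating-like clusters Cd74 was 0.22 and Mcm5 -0.013 (expanded against single cells), without the cluster led by myeloid genes Hbb-bs was -2.54, and without the largest clonotypes Pdcd1 was 0.17 and Ifng 0.071. The main fits have 4 sums and 1 residual degree of freedom, and every test speaks for these 2 mice only.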

Other observations

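The comparison of expanded with single Vβ3 clonotypes, of Vβ3 with TRBV23 cells, and the test of Vβ3 RNA in TRBV23 cells were chosen after the data were seen, as were the genes named here outside the naming rule. Within Vβ3 cells, clonotypes of 2 or more cells differed from clonotypes of 1 cell in 1265 of 11301 genes, 755 higher and 510 lower, in 98 without the mouse block, in 723 after thinning, and in 294 with 1 cell per clonotype, 160 higher and 134 lower. Ccl5, a chemokine gene of effector cells, was 1.21 higher on the log2 scale (SE 0.0180), the perforin gene Prf1 1.20 higher (SE 0.143) and the granule protein gene Nkg7 0.95 higher. The proenkephalin gene Penk was 1.70 higher (SE 0.127). Id3 was -0.74 (SE 0.0539) and Tcf7 -0.70 (SE 0.0403), both lower in the expanded clonotypes, while Il21 lay at 0.01 (adjusted p = 0.972) and Pdcd1 at 0.12 (adjusted p = 0.232). All 22 proliferation genes rose (camera adjusted p = 5.08e-86), 10 of 14 Treg genes rose and 2 fell (1.02e-09), 8 of 12 cytotoxic genes rose (1.12e-26), 10 of 14 naive genes fell (3.68e-17), and 5 of 13 Tfh genes fell (0.00241), with an adjusted p of 0.452 for each of these lists with an estimated correlation. Markers of other cells rose as well: 2 of 2 erythroid genes (median 3.33), 2 of 3 dendritic cell genes, 2 of 5 myeloid genes and Ighm.

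With cluster composition matched, Vβ3 cells still had higher Il12rb2, which encodes an interleukin 12 receptor chain (log2 1.10, SE 0.0985), Klrg1 (0.98, SE 0.0737) and Il10 (0.85, SE 0.100), and lower Spp1 (-3.17, SE 0.142) and Prf1 (-0.89, SE 0.0893). Within the cluster led by Sostdc1 and Id3 alone, 159 of 10698 genes differed, 35 higher and 124 lower in Vβ3 cells. The immediate early genes Nr4a1 (-1.07, SE 0.0989) and Nr4a3 (-1.50, SE 0.195), the chemokine gene Ccl4 (-1.33) and Il2 (-2.14) were lower there, and Bcl2l11 was 0.74 higher (SE 0.128). Directly against TRBV23 cells, Vβ3 cells also had lower Nr4a1 (-0.39, SE 0.0722), Nr4a3 (-0.79, SE 0.142) and Egr2 (-0.50, SE 0.0858), and higher Penk (0.95, SE 0.0815).

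The likeness of TRBV23 and Vβ3 cells was weighed against 3 technical explanations and a biological one. At most 1.79% of TRBV23 cells in a mouse had 2 or more Trbv26 UMIs, far below the slope of 82.6% of their profile on that of Vβ3 cells, which argues against Vβ3 cells or RNA among them. With separate comparison cells r was 0.815 across genes, above the highest simulated value, which argues against shared comparison cells, and with clonotypes of 1 cell alone r was 0.885, where the next V gene had 0.142, which argues against small clonotypes as the whole cause. A superantigen of the host seen by both V segments may underlie the shared profile, but it cannot be told apart from other causes here, since the design has 1 kind of host.

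CDR3 amino acid sequences shared between the mice numbered 119 for Vβ3, 18 for TRBV23 and 35 for the other V genes, out of 1387 and 1376, 629 and 500, and 1079 and 1379 sequences per mouse. Per 1000000 pairs of sequences the shared ones were 62.4, 57.2 and 23.5, but most pairs of the other V genes join 2 different V genes and cannot be shared, and over pairs within the same V gene the rates were 62.4, 57.2 and 298.1. In mouse 1 a TRBV14 clonotype of 60 cells with the TRB CDR3 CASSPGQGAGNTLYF and a TRBV13-3 clonotype of 39 cells with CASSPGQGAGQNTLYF both used TRAV6D-6 and TRAJ49. TRBJ1-1 was used by 15.3% and 15.4% of Vβ3 clonotypes, and TRBJ2-3 by 15.1% and 14.8% of TRBV23 clonotypes.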
